A study of Rattus norvegicus with 58 samples.

How the data were processed

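Liver RNA of 58 male rats was hybridised to Affymetrix rat genome arrays, 1 array per rat, after two-cycle amplification and biotin labelling, per the labels' protocols. The rats were 17 weeks old and had been fasted overnight, per the labels. Of these arrays, 46 came from heterogeneous stock (HS) rats, an outbred colony descended from several inbred strains, and 12 from 6 inbred strains with 2 arrays each. The HS rats were grouped as glucose-normal (23 arrays) or glucose-intolerant (23 arrays) from the sample titles and the design text, since one description of the intolerant rats joins the words normal and intolerance.

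The authors' deposited table holds log2 expression values for 31042 probe sets. The values run from 1.86 to 15.0, and the array medians lie between 5.33 and 5.39, so the arrays had been brought to a common scale before deposit. The method of background correction, summarisation and normalisation is not given in the sources used here. The submitters' processing notes name Partek, without a version. Scan dates, cages and families are not given in the sources used here, so no batch could be tested. Signal on an array has no read depth, and the number of arrays limits the precision.

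Probe sets were named from the platform annotation, with symbols checked through gene identifiers against the GRCr8 annotation, where 14167 of 14217 genes were found. A single symbol belonged to 20826 probe sets, several symbols to 436 and none to 9780. Probe sets with several symbols or none were tested but not named. For statements on a gene, the probe set with the highest mean over all arrays was used, giving 14217 genes. No manufacturer control probe sets were among the values analysed here, so the planned comparison of 3 prime and 5 prime control signals was not run.

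Tests were run in R 4.3.3 with limma 3.58.1 (lmFit and eBayes) on the log2 values as deposited, with no filter, and p-values were adjusted by the Benjamini-Hochberg method over the 31042 probe sets with a threshold of 0.05. The glucose groups were compared among the 46 HS arrays with 44 residual degrees of freedom. The strains were compared among the 12 inbred arrays with 6 residual degrees of freedom, first by a moderated F test over the 6 strains, then for each strain against the mean of the other 5. P-values therefore measure the spread between these arrays. Gene lists were tested over the 14217 genes with camera at a preset correlation between genes of 0.01, with camera at an estimated correlation, and with fry, which asks whether the genes of a list move on balance one way. These p-values were adjusted over 36 lists for the glucose groups and over 216 pairs of list and strain. The share of each list that differed among strains was compared with all other genes by Fisher's exact test, two-sided, adjusted over the 36 lists. Fisher's test takes genes as independent and the other genes include dim ones, so its p-values may be too small.

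The lists, the rule for named genes and the other settings were fixed before the data were examined. Named genes of the glucose comparison were those past the threshold or, with none past it, the 20 genes of smallest p, plus genes of hepatic glucose and lipid metabolism chosen beforehand and the 2 members of smallest p in each list. Named genes of a strain were the 3 highest and the 3 lowest among called genes whose 2 arrays both lay beyond all 10 other inbred arrays, plus up to 4 called members of each list.

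The tests were checked on simulated data. Of 31042 simulated probe sets with the means and spreads of the HS rats, 200 were shifted, and the glucose comparison recovered 73.1% of shifts of 0.25, 92.5% of shifts of 0.5 and 100% of shifts of 1 on the log2 scale. In the same kind of simulation for WKY, 31.3% of shifts of 0.5, 97.0% of shifts of 1 and 100% of shifts of 2 were recovered. The simulated noise was normal and independent between probe sets, while real probe sets vary together. Recovery also depends on the number of probe sets shifted, so these shares may not hold for the real comparisons. Alternatives covered the brighter probe sets alone, 1 probe set per gene, quantile normalisation, centring on the array median, trend and robust variance estimation, array weights, a residual component as a covariate, a plain linear model, other groupings of arrays, the replicate number as a block and leaving out single arrays.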

Results

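Liver gene expression was measured on arrays in 46 HS rats, of which 23 were glucose-intolerant and 23 had normal glucose tolerance, and in 12 rats of the inbred strains ACI, BN, BUF, F344, M520 and WKY. HS rats are outbred animals whose genomes are mosaics of inbred founder strains. No 2 arrays held identical values, and the correlation between the 2 arrays of a strain ran from 0.989 in BUF to 0.997 in ACI. The labels do not say that the 2 arrays of a strain came from separate litters or days, so the p-values measure only the spread between these arrays. All values are log2 expression, so that a difference of 1 is a 2-fold difference.

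The first comparison asked which liver transcripts differ between glucose-intolerant and glucose-normal HS rats. No gene passed the test at this threshold. The genes of smallest p included Snx13, a sorting nexin, which averaged 3.64 ± 0.39 (SD, n = 23) in intolerant and 4.23 ± 0.49 (SD, n = 23) in normal rats. Psmb8, a subunit of the immunoproteasome, averaged 9.95 ± 0.27 in intolerant and 9.56 ± 0.31 in normal rats (SD, n = 23 each), and Spin2b, a spindlin family member, averaged 7.70 ± 0.69 against 6.40 ± 1.25. Each of these 3 genes had an adjusted p = 0.179 in limma's moderated test.

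With limma, 0 of 31042 probe sets passed an adjusted p of 0.05, and the smallest adjusted p was 0.137. At an unadjusted p under 0.05 there were 2483 probe sets, 985 higher and 1498 lower in intolerant rats. The average expected by chance is 1552, but probe sets vary together. Of 100 splits of these rats into groups of 23, the real one included, 16 gave 2483 or more, so chance is not excluded. A plain linear model without variance moderation also called 0. Array weights, however, called 12 probe sets, and a fit with the first residual component as a covariate called 185, a number that 23 of 100 splits of these rats into groups of 23 reached. Chosen after seeing the data, a fit without the 5 rats of highest score on an axis of expression that also separates arrays of a strain called 33. The 95% interval of the difference lay inside ±0.5 for 97.8% of probe sets and inside ±1 for 99.7%. These shares include probe sets of dim signal, whose narrow intervals may not bound a difference in transcript level.

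Among the 20 genes of smallest p, the intolerant rats had the higher mean for Golt1b (0.17), Ccnyl1 (0.15), Uxs1 (0.16), Echdc2 (0.13) and Elovl5 (0.27), besides Psmb8 and Spin2b. Elovl5 is an elongase of polyunsaturated fatty acids. The intolerant rats had the lower mean for Zcchc9 (-0.33), Fxyd6 (-0.25), Nptx1 (-0.17), Cntn5 (-0.17), Myoz1 (-0.17), Apon (-0.23), Tceal9 (-0.23), Gabbr1 (-0.41), Brinp1 (-0.21), Txndc16 (-0.19), Osbpl3 (-0.25) and Mindy4 (-0.19), besides Snx13. Apon encodes an apolipoprotein and Gabbr1 a receptor subunit for GABA. Their adjusted p ran from 0.179 to 0.237, so none is called. In both groups Snx13, Nptx1, Golt1b, Cntn5, Myoz1 and Brinp1 averaged below the array medians, so their signal is dim.

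Genes of hepatic glucose and lipid metabolism were not called either. Igfbp2, which binds insulin-like growth factors, averaged 7.01 ± 0.85 in intolerant and 7.71 ± 0.74 in normal rats (SD, n = 23 each), a difference of -0.69 ± 0.23 (SE) with p = 0.00355 and adjusted p = 0.421. Pklr, the liver pyruvate kinase of glycolysis, differed by 0.29 ± 0.10 (SE) with adjusted p = 0.433. Among lipogenic enzymes, Scd, the desaturase that makes monounsaturated fatty acids, differed by 0.94 ± 0.41 (SE, adjusted p = 0.562) and Fasn, the fatty acid synthase, by 0.40 ± 0.18 (SE, adjusted p = 0.576). Irs1, an adaptor of the insulin receptor, differed by -0.16 (adjusted p = 0.563), and Igfbp1 by -0.38 (adjusted p = 0.659). Tpcn2, an ion channel of endosomes and lysosomes, averaged 6.40 ± 1.04 in intolerant and 6.97 ± 0.55 in normal rats (SD, n = 23 each), a difference of -0.57 ± 0.24 (SE, adjusted p = 0.539).

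For Pck1, the gluconeogenic carboxykinase, the difference was -0.01 ± 0.03 (SE). Differences for Fbp1 (0.05), Gckr (0.13), Slc2a2 (0.13), Insr (-0.07), Irs2 (-0.06), Srebf1 (0.22), Mlxipl (-0.05), Cpt1a (-0.05), Pdk4 (0.17) and Fgf21 (0.14) had adjusted p of 0.646 or more.

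**Figure D1:**
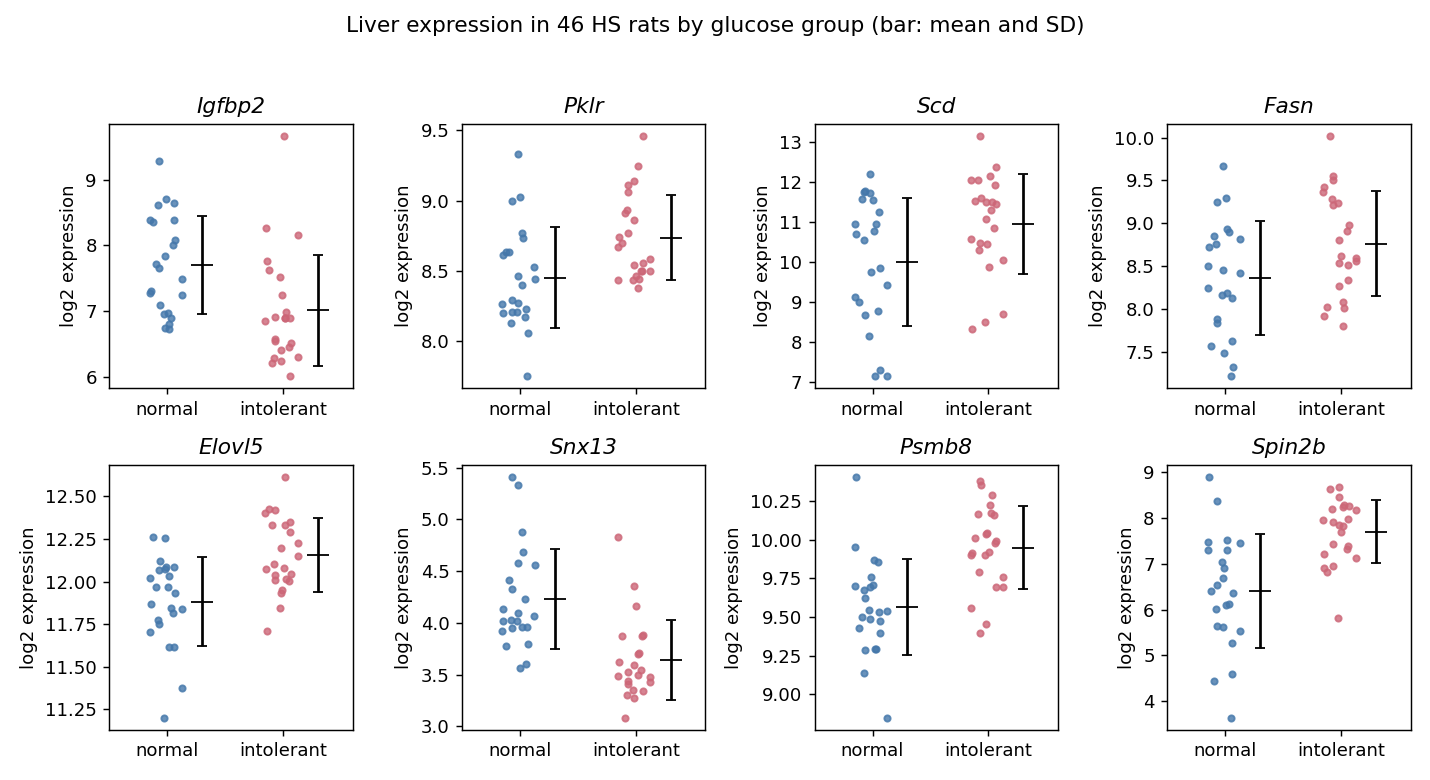
Log2 expression (vertical axes) of 8 genes in glucose-normal and glucose-intolerant HS rats (horizontal axes); each point is 1 rat and the bars give the mean and SD of 23 rats. The groups overlap for every gene drawn, and Snx13 and Psmb8 have an adjusted p of 0.179.

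Of 36 gene lists, 3 were called higher in intolerant rats by camera with a preset correlation. In the oxidative phosphorylation list, 34 of 42 members had a higher mean in intolerant rats, with a median difference of 0.05 and 0 members called (adjusted p = 7.16e-06 for the list, and adjusted p = 0.842 with an estimated correlation). In the list of fatty acid and triglyceride synthesis, 17 of 21 members had a higher mean, with a median difference of 0.12 (adjusted p = 0.00028, and adjusted p = 0.381 with an estimated correlation). In the list of glycolysis and glucose phosphorylation, 11 of 14 members had a higher mean, with a median difference of 0.04 (adjusted p = 0.00158, and adjusted p = 0.381 with an estimated correlation). No member of these lists was called over all genes, while adjusted over the list alone 0, 1 and 2 members passed. The 1 lipogenic member was Elovl5, and the 2 glycolytic members were Pklr and the enolase Eno1 (0.21).

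By fry 0 of the 36 lists passed, at adjusted p of 0.581, 0.518 and 0.467 for these 3. With an estimated correlation 0 lists passed. Markers of other liver cell types had the opposite sign without passing: 1 of 17 liver endothelial markers and 1 of 18 Kupffer cell and macrophage markers had a higher mean in intolerant rats (adjusted p = 0.137 and 0.258). Among their members, Stab2 differed by -0.23, Pecam1 by -0.19 and Clec4f, a Kupffer cell lectin, by -0.24.

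Other lists of the glucose comparison did not pass, and single members of small p are given as values. Among histocompatibility genes, RT1-CE10 averaged 8.74 ± 1.35 in intolerant and 7.63 ± 0.77 in normal rats (SD, n = 23 each, adjusted p = 0.271), and adjusted over the list alone 2 of 20 members passed. Apoa4, an apolipoprotein of triglyceride-rich particles, differed by 0.42 ± 0.11 (SE, adjusted p = 0.238). Bckdhb, a subunit of branched-chain keto acid dehydrogenase, differed by 0.30 ± 0.08 (SE, adjusted p = 0.282). Cyp7b1, an oxysterol hydroxylase, differed by -0.73 ± 0.27 (SE, adjusted p = 0.497). The bile duct keratin Krt19 differed by -0.22 ± 0.07 (SE, adjusted p = 0.379) and Lect2, a pericentral hepatocyte gene, by -0.23 ± 0.07 (SE, adjusted p = 0.362). Each of Apoa4, Bckdhb, Krt19 and Lect2 was the 1 member of its list to pass when adjusted over the list alone.

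The second comparison asked which transcripts differ among the 6 inbred strains. Histocompatibility and interferon response genes differed most often, followed by glucocorticoid targets and genes of drug metabolism. Of 20 histocompatibility genes 18 (90.0%) and of 26 interferon response genes 21 (80.8%) passed the F test, against 13.8% of all genes (Fisher's exact test, adjusted p = 7.84e-13 for both lists). Members of a list can vary together and dim genes count among all genes, so p-values of this test may be too small. The share was 68.8% of glucocorticoid targets (11 of 16, adjusted p = 6.71e-06) and 60% of genes of xenobiotic metabolism (21 of 35, adjusted p = 3.05e-09). By the F test 0 of 42 oxidative phosphorylation genes (adjusted p = 0.00974) and 0 of 30 cytosolic ribosomal protein genes (adjusted p = 0.0535) differed. Against the mean of the other strains, however, Atp5pf (-0.72) and Uqcrfs1 (-0.55) were lower in BUF, Cox7b (0.57) was higher and Rps16 (-0.39) lower in M520. As lists, oxidative phosphorylation was called higher in F344 and M520 (adjusted p = 0.00991 and 0.00573, and adjusted p = 0.773 with an estimated correlation for both) and lower in WKY (adjusted p = 0.0376, and adjusted p = 0.826 with an estimated correlation).

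In all, limma's F test called 3700 of 31042 probe sets (11.9%), of which 1969 had a range of strain means of 1 or more and 113 a range of 3 or more. The F test called 2130 and 2241 probe sets without ACI array 1 or 2, 2437 without M520 array 1 and 5945 without BUF array 1. Over genes, 1960 of 14217 were called. Many members also differed in the lists of fatty acid and triglyceride synthesis (11 of 21, adjusted p = 0.000185), urea cycle and amino acid breakdown (15 of 30, adjusted p = 1.69e-05) and Kupffer cell and macrophage markers (9 of 18, adjusted p = 0.00119). In all, 18 of the 36 lists departed from the share of other genes.

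Against the mean of the other 5 strains, 50 of 216 pairs of list and strain were called by camera with a preset correlation, 13 by fry and 0 with an estimated correlation, where adjusted p = 0.531 was the lowest. List statements for single strains therefore rest on the preset correlation and on the number of called members. Lists with 0 called members rest on the preset correlation alone. Among HS rats that setting called 3 or more of 36 lists in 87 of 100 splits, the real one included. Its list p-values for strains may therefore be too small as well, but such splits were not run for strains.

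BN livers had less of several lipogenic and interferon-related transcripts than the other strains. Scd differed by -4.60 ± 0.35 (SE, adjusted p = 1.91e-05), and Srebf1, the transcription factor of lipogenesis, differed by -1.70 (adjusted p = 0.008). A second probe set of Srebf1 differed by -0.88 without being called. Echdc2, an enoyl-CoA hydratase domain protein, differed by -6.42 ± 0.10 (SE, adjusted p = 1.86e-11). Its level in BN, 3.74, lies below the array medians, as does that of Scd, 4.79, so the exact size of these differences is uncertain. AKR1C3l1, an aldo-keto reductase, differed by -3.58. BN livers had more Cyp17a1, an enzyme of steroid hormone synthesis, at 5.91 ± 0.31 (SE, adjusted p = 1.16e-06), more of the collagen cross-linking enzyme Lox at 5.06 and more Wdr90 at 3.96. For Lox, WKY was also high, at 7.79 against 9.37 in BN.

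In BN, 5 members of fatty acid and triglyceride synthesis were lower and 1, Lpin1 (2.57), was higher (list adjusted p = 2.09e-05, and adjusted p = 0.531 with an estimated correlation). With p adjusted over the list alone, 12 were lower and 2 higher. Of 26 interferon response genes 12 were lower and 1 higher, with Igtp at -2.06, Oas1a at -1.98 and Psmb8 at -1.57 (list adjusted p = 6.33e-12, and adjusted p = 0.531 with an estimated correlation). Another probe set of Igtp differed by -1.35 without being called. Of 20 histocompatibility genes 8 were lower and 2 higher, with the class I gene RT1-A at -2.67 (list adjusted p = 3.92e-06, and adjusted p = 0.531 with an estimated correlation). In these lists 18 interferon response genes and 13 histocompatibility genes were lower when adjusted over the list alone.

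Glucocorticoid targets were higher in BN, with 5 of 16 called and 0 lower, among them Fkbp5 (1.97), Igfbp1 (2.22) and the metallothionein Mt2A (2.32) (list adjusted p = 0.000278, and adjusted p = 0.765 with an estimated correlation). Another probe set of Fkbp5 differed by 0.77 without being called. Immediate early genes such as Egr1 (1.99) were also higher, 5 of 23 called (list adjusted p = 0.00398, and adjusted p = 0.765 with an estimated correlation). There were 9 glucocorticoid targets and 7 immediate early genes higher when adjusted over the list alone. In the same arrays 6 of 17 endothelial markers were higher, with Emcn at 1.08 (list adjusted p = 5.21e-07, and adjusted p = 0.765 with an estimated correlation), and 2 of 18 Kupffer cell markers, Cd163 (0.90) and Clec4f (0.88). The Kupffer cell and macrophage list had the higher mean in 16 of 18 cases, with 10 higher when adjusted over the list alone (list adjusted p = 3.05e-05, and adjusted p = 0.773 with an estimated correlation). BN had 1454 called probe sets, 808 higher and 646 lower, and 498 or 698 without its array 1 or 2.

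WKY livers had more of many immune transcripts. Of 26 interferon response genes 16 were higher and 1 lower, with Mx2 at 2.21 ± 0.19, Usp18 at 2.04 ± 0.21 and Mx1 at 1.74 ± 0.22 (SE, list adjusted p = 4.06e-13, and adjusted p = 0.531 with an estimated correlation). Of 20 histocompatibility genes 11 were higher and 3 lower (list adjusted p = 5.21e-07, and adjusted p = 0.531 with an estimated correlation). Among these, RT1-N2 was higher by 4.45 ± 0.19 (SE, adjusted p = 2.53e-07) and RT1-A3 by 3.38 ± 0.17 (SE, adjusted p = 6.77e-07), while RT1-T24-4 differed by -3.25. A second probe set of RT1-A3 had the same sign without being called. The other strains averaged 4.10 for RT1-N2 and 4.23 for RT1-A3, below the array medians, so the exact size of both differences is uncertain. Adjusted over the list alone, 21 interferon response and 13 histocompatibility genes were higher.

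Cxcl13, a chemokine for B cells, was higher in WKY by 3.26 ± 0.16 (SE, adjusted p = 6.21e-07). Mlc1, a membrane protein, differed by -4.67 ± 0.11 (SE, adjusted p = 1.58e-09) and Eri2, an exonuclease, by -4.59 ± 0.13 (SE, adjusted p = 5.22e-09), while a second probe set of Eri2 differed by only -0.88. In WKY, Mlc1, at 4.49, and Eri2, at 3.80, lie below the array medians, so the exact size of both differences is uncertain. Of 35 genes of xenobiotic metabolism 13 were lower and 2 higher, with the alcohol dehydrogenase Adh4 at -2.13 and Aldh1a1 at -1.92 (list adjusted p = 5.21e-07, and adjusted p = 0.765 with an estimated correlation). Matrix and stellate cell genes were higher in 6 of 25 cases and lower in 0, with Loxl1 at 1.94 and the collagen Col1a2 at 1.15 (list adjusted p = 3.92e-06, and adjusted p = 0.765 with an estimated correlation). Adjusted over the list alone, 16 xenobiotic genes were lower and 11 matrix genes higher. Kupffer cell and macrophage markers also had the higher mean in 16 of 18 cases, with 2 called, among them Clec4f (0.97), and 8 when adjusted over the list alone (list adjusted p = 0.000212, and adjusted p = 0.773 with an estimated correlation). WKY had 1471 called probe sets, 829 higher and 642 lower, and 487 without its array 1.

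ACI livers had more of several detoxifying enzymes. Gsta3, a glutathione transferase, was higher by 2.99 ± 0.31 (SE, adjusted p = 0.000342) and the quinone reductase Nqo1 by 1.99 ± 0.20 (SE, adjusted p = 0.000297). Gsta3 was also called higher in BN, by 2.17 (limma, adjusted p = 0.00177), and F344, at 4.51, lowers the mean of the other 5 strains. The level of Nqo1 was similar in BUF (10.2 against 10.3 in ACI). Of 35 genes of xenobiotic metabolism 6 were higher and 1, Adh4 (-1.23), lower (list adjusted p = 3.92e-06, and adjusted p = 0.765 with an estimated correlation). NRF2 targets, genes of the oxidative stress response, were higher in 4 of 16 cases (list adjusted p = 3.05e-05, and adjusted p = 0.736 with an estimated correlation). These numbers were 15 and 6 when adjusted over the list alone. The named genes of ACI were RGD1309362 (6.01 ± 0.15, SE, adjusted p = 2.67e-09), the ubiquitin-like modifier Ubd (4.27) and Tmem14a (3.33) as higher, and Crebl2 (-2.17), Pdzrn3 (-1.92) and Vsig10 (-1.85) as lower. A second probe set of Crebl2 had the opposite sign. Ubd was nearly as high in F344 (9.62 against 10.4 in ACI), and Tmem14a in WKY (7.70 against 8.34). ACI had 752 called probe sets, 417 higher and 335 lower, 148 and 177 without its array 1 or 2 and 1452 without BUF array 1.

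BUF livers had less of the cytochrome P450 transcript Cyp2c7, at -4.02 ± 0.23 (SE, adjusted p = 2.81e-06), and less Cyp4a8, at -3.01, which was as low in BN (4.47 against 4.65 in BUF). In the list of fatty acid oxidation and PPAR alpha targets 6 of 28 genes were lower and 0 higher, including Ppara itself at -0.85 (list adjusted p = 4.12e-05, and adjusted p = 0.765 with an estimated correlation). Heat shock genes were lower in 6 of 15 cases, with Dnajb4 at -0.70 (list adjusted p = 5.9e-05, and adjusted p = 0.765 with an estimated correlation). Adjusted over the list alone, 11 and 7 were lower. Among Kupffer cell markers 4 of 18 were lower and 1, Lyz2 (1.31), higher (list adjusted p = 0.000329, and adjusted p = 0.773 with an estimated correlation). Lists of matrix and stellate cell markers (4 of 25 lower, adjusted p = 0.00935, and adjusted p = 0.773 with an estimated correlation) and endoplasmic reticulum stress (4 of 24 lower and 1 higher, adjusted p = 0.00362, and adjusted p = 0.765 with an estimated correlation) were called lower as well. When adjusted over the list alone, 6 and 7 were lower. BUF array 2 had the lowest median correlation with the other arrays of any array, at 0.976, against 0.988 for BUF array 1. On the axis of expression that also separates arrays of a strain, the 2 BUF arrays stood 3.76 HS SDs apart. The BUF list results may therefore depend on array 2.

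Sort1, a sorting receptor of lipoprotein metabolism, was higher in BUF by 2.44 ± 0.10 (SE, adjusted p = 2.49e-07), with a second probe set called the same way. Ugt2b, a glucuronosyltransferase, was higher by 4.49 and Clca2 by 2.64, while Pip4p2 differed by -2.14 and Adam22 by -1.85. Of 2 other probe sets of Adam22, only 1 had the same sign. The level of Ugt2b was not particular to BUF, at 13.4 there, 13.2 in BN and in M520, and low in ACI (5.59), WKY (5.29) and F344 (7.18). BUF had 1789 called probe sets, 774 higher and 1015 lower, a balance that depends on scaling (883 and 931 with quantile normalisation, 716 and 1065 with median centring). Its 2 arrays correlated least of the 6 strains, and the number called was 4255 without array 1 and 229 without array 2. It was 936 and 931 without ACI array 1 or 2, and 1150 and 1106 without M520 array 1 or 2.

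M520 livers had less of the class II histocompatibility gene RT1-Bb, at -3.03 ± 0.13 (SE, adjusted p = 2.81e-07), and BUF had as little of it (-2.95). Of 20 histocompatibility genes 11 were lower and 1 higher (list adjusted p = 9.79e-06, and adjusted p = 0.531 with an estimated correlation). Kupffer cell and macrophage markers were lower in 6 of 18 cases, with Clec4f at -0.80 and Cd14 at -0.77 (list adjusted p = 4.71e-05, and adjusted p = 0.773 with an estimated correlation). Adjusted over the list alone, 13 and 10 were lower. Probe sets of these polymorphic genes can contradict each other. RT1-Ba, singled out after its values were seen, was counted as lower in M520 (-1.08) while its other probe set was called higher (2.25), and in WKY the values were 1.44 and -2.34. The apolipoproteins Apoa1 (-0.69) and Apoa2 (-0.64) were lower as well. Cyp2c12, known as a female-type P450 of rat liver, was higher by 2.49 ± 0.23 (SE, adjusted p = 0.000154).

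The named genes of M520 were Ndnf, a secreted neurotrophic factor (3.47 ± 0.11, SE, adjusted p = 1.77e-08), Ifgga2l1 (2.70) and Eri2 (2.57) as higher, and Stac3 (-2.80), Cyp17a1 (-2.68) and Pyroxd2 (-2.57) as lower. For Ndnf the other 10 inbred arrays ran from 3.28 to 3.65, below the array medians, so the exact size of its difference is uncertain. Second probe sets of Eri2 (0.26) and Pyroxd2 (-0.41) had the same sign with much smaller differences that were not called. The level of Ifgga2l1 was 9.45 in M520 and 9.29 in ACI, and WKY, at 3.80, lowers the mean of the other 5 strains for Eri2. Cyp17a1 is at 4.99 in M520, and BN, at 12.2, raises the mean of the other 5 strains. M520 had 1445 called probe sets, 588 higher and 857 lower (639 and 739 with quantile normalisation, 543 and 966 with median centring), 230 and 319 without its array 1 or 2, 846 and 879 without ACI array 1 or 2, and 2296 without BUF array 1.

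F344 livers had less Cyp4v3, a fatty acid hydroxylase, at -5.96 ± 0.09 (SE, adjusted p = 9.9e-12), while a second probe set, called the same way, differed by -2.41. Gsta3 differed by -3.37 ± 0.31 (SE, adjusted p = 0.000144) and RGD1309362 by -2.86, where ACI, at 10.1, raises the mean of the other 5 strains and BUF, at 3.13, is close to F344, at 2.74. In F344, Cyp4v3, at 5.33, lies near the array medians, and Gsta3, at 4.51, and RGD1309362 lie below them. The exact size of these differences is therefore uncertain. Scrn1 (2.92), AA926063 (2.66) and Mst1, a hepatocyte growth factor-like protein (1.86), were higher. Mst1 was at 10.9 in F344, 10.7 in ACI and 10.7 in BN, so its difference comes from lower levels in BUF, M520 and WKY. Scd was higher by 2.59 ± 0.35 (SE, adjusted p = 0.00271), where BN, at 4.79, lowers the mean of the other 5 strains, and Scd2 differed by -0.90. The list of fatty acid and triglyceride synthesis had a median difference of 0.43 (list adjusted p = 0.000177, and adjusted p = 0.678 with an estimated correlation), with 5 members higher and 1 lower when adjusted over the list alone. In the same arrays 28 of 30 ribosomal protein genes had a lower mean with 0 called (list adjusted p = 1.82e-05, and adjusted p = 0.765 with an estimated correlation). Lists of glucocorticoid targets (adjusted p = 0.013, and adjusted p = 0.765 with an estimated correlation) and bile duct markers (adjusted p = 0.0379, and adjusted p = 0.773 with an estimated correlation) were called lower. The lists of endothelial (15 of 17 lower, adjusted p = 0.0642) and Kupffer cell markers (16 of 18 lower, adjusted p = 0.134) did not pass. F344 had 499 called probe sets, 255 higher and 244 lower, 195 and 179 without its array 1 or 2 and 328 without ACI array 1.

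**Figure D2:**
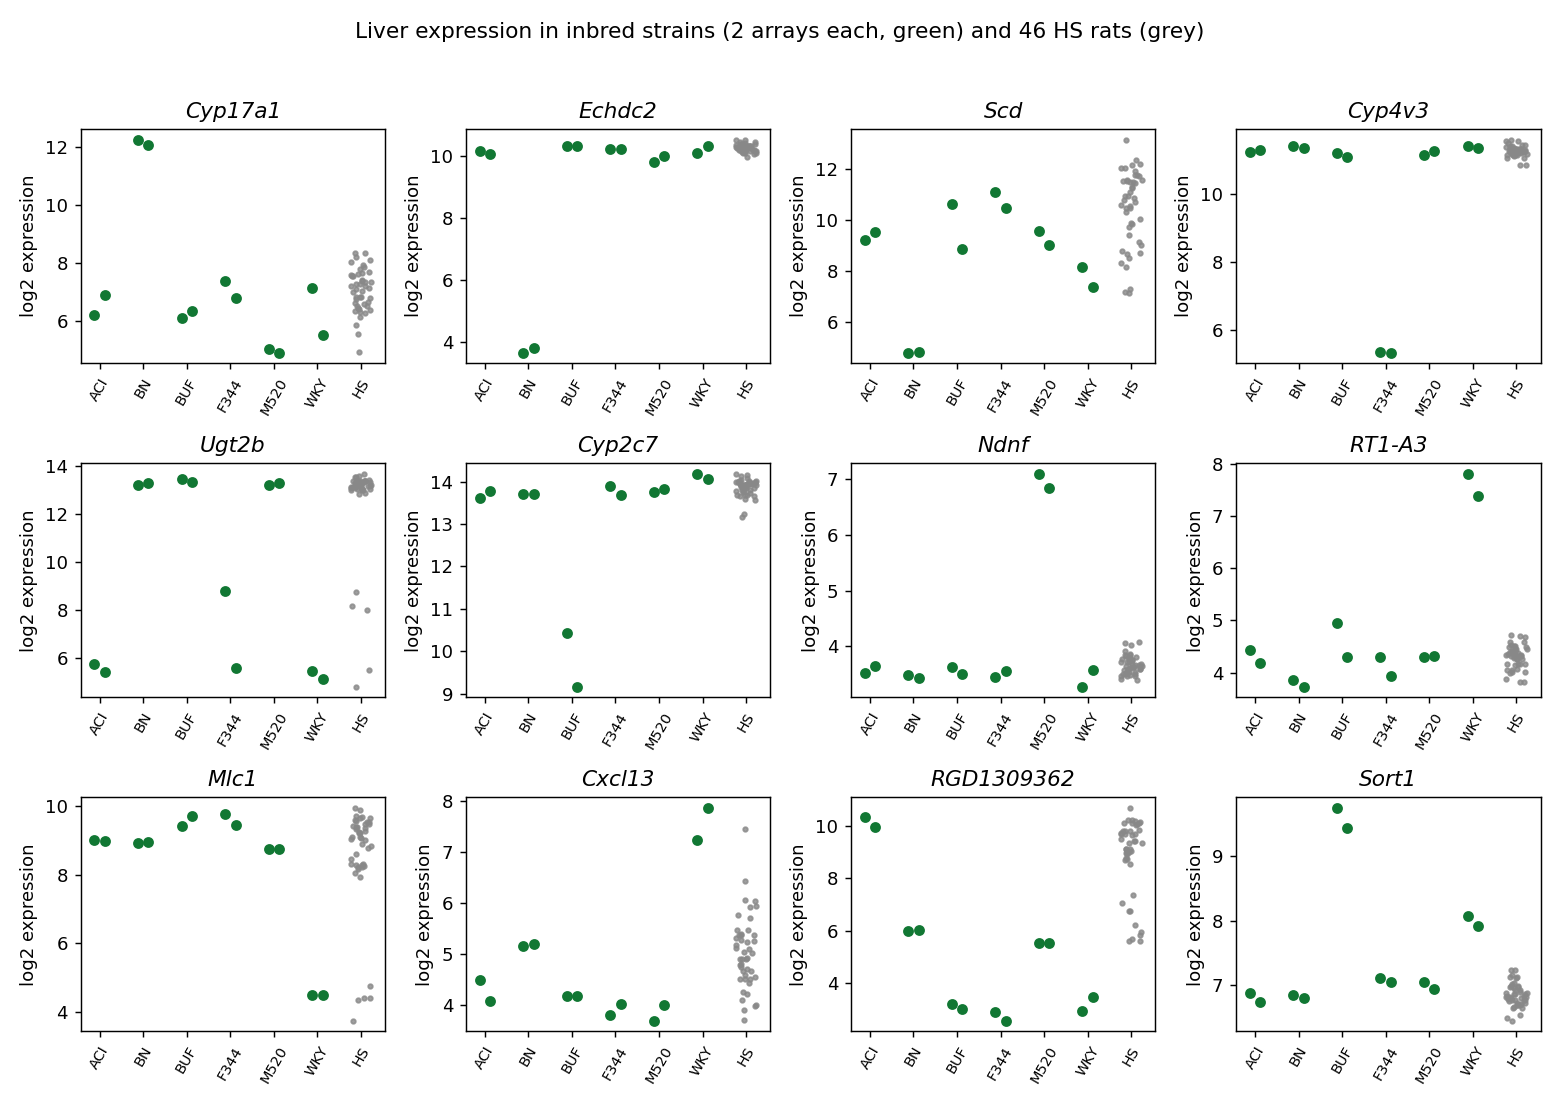
Log2 expression (vertical axes) of 12 genes named for single strains, by strain on the horizontal axes; green points are the 2 arrays of each inbred strain and grey points are 46 HS rats. Echdc2 is at 3.74 in BN and between 9.97 and 10.5 in HS rats, and Cyp17a1 is at 12.2 in BN and at most 8.36 in HS rats.

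**Figure D3:**
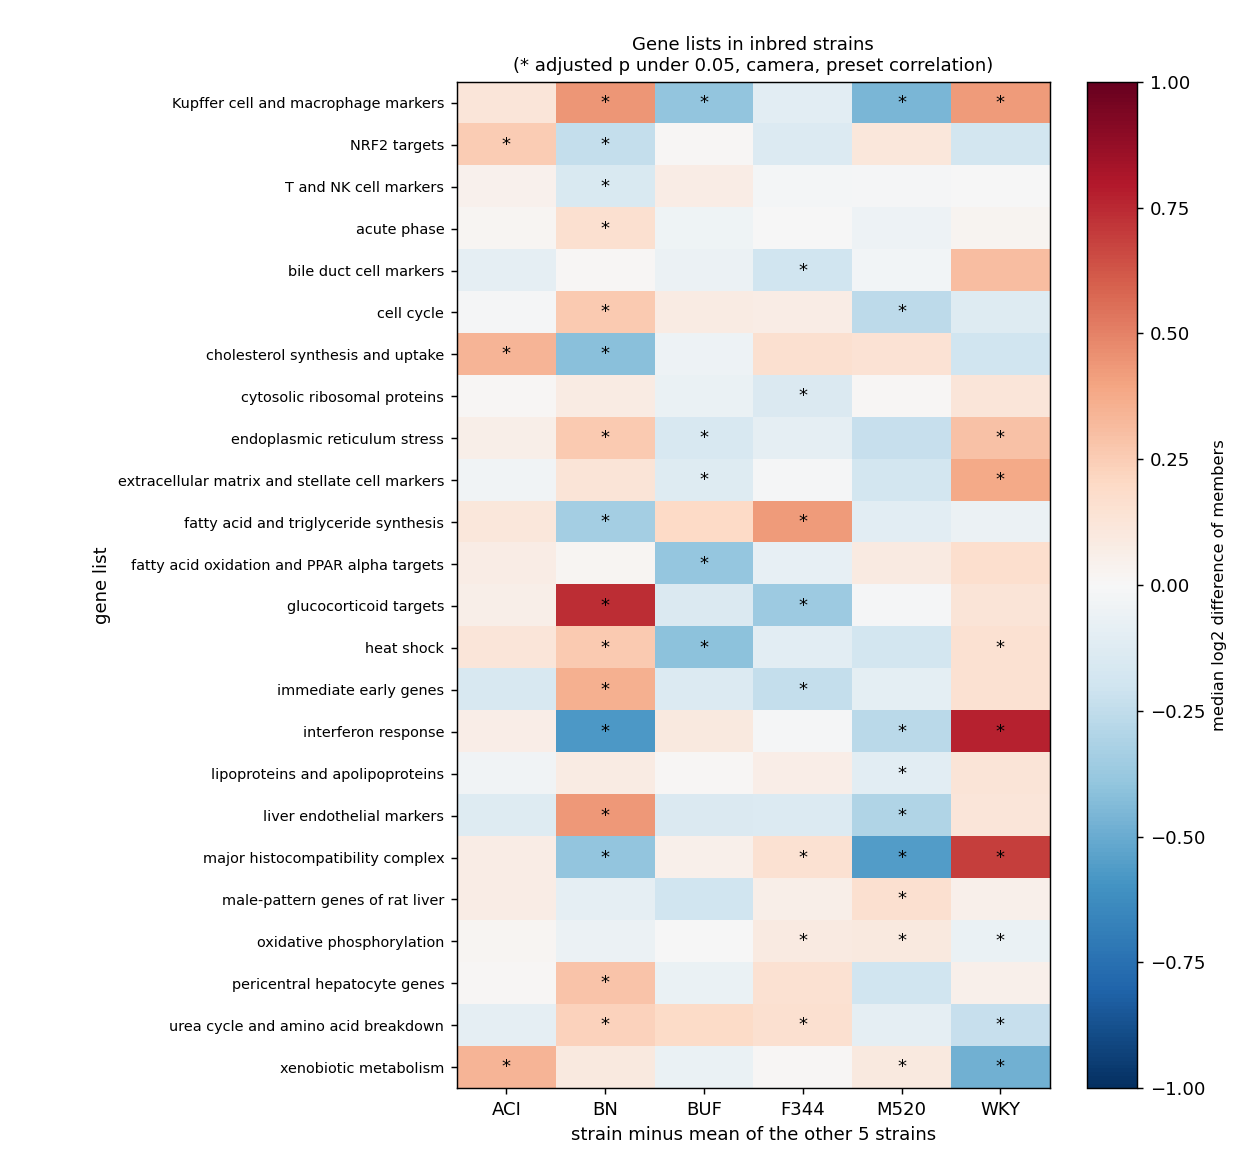
Median log2 difference of list members in each strain (horizontal axis) against the mean of the other 5 strains, for lists called in at least 1 strain (vertical axis); red is higher, blue is lower, and a star marks an adjusted p under 0.05 by camera with a preset correlation. The interferon response list has a median of -0.58 in BN and 0.77 in WKY.

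The last comparison asked whether transcripts that vary among HS rats also differ among strains. Of the 1000 most variable probe sets in HS rats, 541 (54.1%) differed among the 6 strains by limma's F test, against 11.9% of all probe sets. Across probe sets, which are not independent replicates, the SD within the glucose groups of HS rats correlated with the SD of strain means (Spearman's rho = 0.640). It also correlated with the SD between arrays of a strain (rho = 0.566), and the median SD was 0.17 among HS rats and 0.16 within strains.

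Genes named for a strain ranged differently in HS rats. Mlc1, at 4.49 in WKY, ran from 3.74 to 9.94 in HS rats, and Cxcl13, at 7.55 in WKY, ran from 3.71 to 7.45. RGD1309362, at 10.1 in ACI, ran from 5.62 to 10.7. In contrast, Echdc2 ran from 9.97 to 10.5 in HS rats and was at 3.74 in BN, and Cyp4v3 ran from 10.9 to 11.6 in HS rats and was at 5.33 in F344. Sort1 reached 7.23 in HS rats and was at 9.58 in BUF.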

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

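The 4 results with an axis score as a covariate, or without the 5 HS arrays of highest score, were chosen after seeing the data. All other settings were planned, and the comparison of 3 prime with 5 prime control signals was not run. Probe sets of dim signal were kept, so the size of any difference against a level below the array medians is uncertain.

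The number of probe sets called between the glucose groups was 0 with brighter probe sets alone, with 1 probe set per gene, with median centring, with trend and robust variances, with all 58 arrays in one fit, without moderation, at an adjusted p under 0.10, without the 2 arrays of lowest correlation and with the axis score as a covariate. It was 1 with quantile normalisation, 12 with array weights, 185 with the first residual component as a covariate and 33 without the 5 arrays of highest score; the cause was not tested except for the component, for which other splits of the rats are given among the other observations. Leaving out single rats gave 0 to 3 probe sets: 3 without normal rat 38, and 1 without normal rat 16, 21 or 25 or intolerant rat 13 or 20. Of the 36 lists, 3 were called, 0 with an estimated correlation, 0 by fry, 5 with the axis score as a covariate, and 3 to 5 without single rats, with 5 without intolerant rat 3 or normal rat 6 or 32. Of 5835 values of named genes under other settings, 38 passed the threshold, none reversed.

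Among strains, fewer genes tested gave lower numbers with 1 probe set per gene: 2241 for the F test, 364 for ACI, 923 for BN, 266 for F344, 942 for M520 and 973 for WKY. All 58 arrays in one fit gave 264 for ACI, 960 for BN and 140 for F344, and the cause was not tested. A minimum difference of 1, by its construction, left 1969 for the F test, 226 for ACI, 382 for BN, 292 for BUF, 169 for F344, 244 for M520 and 375 for WKY. Called pairs of list and strain fell from 50 to 0 with an estimated correlation and to 13 by fry. Of 676 values of named strain genes under other settings, 670 stayed past the threshold, none reversed, and 6 were lost, all with 58 arrays in one fit. Of 950 values of called lists, 799 stayed past the threshold and none reversed.

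Leaving out 1 of the 12 inbred arrays leaves a strain with 1 array, which is assumed to vary like the others. The F test then called 2130 to 5945 probe sets: 2130 and 2241 without ACI array 1 or 2, 2437 without M520 array 1 and 5945 without BUF array 1. For ACI the number ran from 148 to 1452, with 148 and 177 without its own arrays 1 and 2 and 1452 without BUF array 1. For BN it ran from 498 to 1676, with 498 and 698 without its own arrays. For BUF it ran from 229 to 4255, with 936 and 931 without ACI arrays 1 and 2, 1150 and 1106 without M520 arrays 1 and 2, 4255 without its own array 1 and 229 without its own array 2. For F344 it ran from 179 to 687, with 195 and 179 without its own arrays and 328 without ACI array 1. For M520 it ran from 230 to 2296, with 230 and 319 without its own arrays, 846 and 879 without ACI arrays 1 and 2, and 2296 without BUF array 1. For WKY it ran from 487 to 1751, with 487 without its own array 1. List and strain pairs ran from 45 to 70.

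With the replicate number as a block, the F test called 3698 probe sets and the lists 50. The labels only number the arrays. The correlation of same-numbered deviations from the strain means ran from -0.197 to 0.572 over 15 pairs of strains, with 5 above 0.1. A pairing of arrays across all strains was not seen, but one in part of the strains is not excluded. With fewer or more of the most variable HS probe sets taken, 298 and 965 differed among strains, as the number taken sets, and leaving out an inbred array gave 437 to 634 of 1000. Spearman's correlation of HS spread with the spread of strain means, across probe sets, was 0.677 with brighter probe sets alone, cause not tested.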

Other observations

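The tests of the axis of expression and of levels found in 1 strain alone were chosen after seeing the data. Clock genes differed among strains, with 9 of 18 past the F test (Fisher's exact test, adjusted p = 0.00119). Nr1d1, a repressor of the circadian clock, differed from the mean of the other 5 strains by -2.49 ± 0.28 (SE) in ACI and -2.68 ± 0.28 in M520, and by 1.45 in BN, 1.46 in F344 and 1.37 in WKY, all past the threshold. Nr1d2 differed by 1.34 in BN and -1.20 in M520, and Cry1 by 1.18 in M520 and -1.22 in WKY. The times of day at which the rats were killed were not analysed here.

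Single genes of bile acid, glycogen and glucose metabolism also differed, singled out after their values were seen. The oxysterol hydroxylase Cyp7b1 was higher in BN by 1.64 and differed by -1.52 in F344 and -1.26 in WKY. Abcc2, a transporter in the list of bile acid synthesis and transport, was higher in WKY by 1.30 ± 0.12 (SE). Ppp1r3b, a glycogen-targeting subunit of protein phosphatase, was higher in M520 by 1.03 and differed by -1.14 in WKY. Pfkfb1, which sets a regulator of glycolysis, was higher in BN by 1.20.

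Other splits of the 46 HS rats into groups of 23 were drawn, 100 in all with the real one. Any split gives 0 or more called probe sets, so the 100 of 100 that did so are no test of chance, and the highest of the others was 1. For probe sets at p under 0.05, 16 of 100 gave the real 2483 or more, with 4427 as the highest other, so chance is not excluded. For lists called with a preset correlation, 87 of 100 gave 3 or more, with 17 as the highest other and 5 as the median of the others, so chance is not excluded for the 3 called lists either. Oxidative phosphorylation was called in 48 of the 100, fatty acid and triglyceride synthesis in 22 and glycolysis in 10. With the first residual component as a covariate, 23 of 100 splits gave the real 185 or more calls and the highest other was 1917, so chance is not excluded for these calls. The splits cannot tell a structure of the samples from a fit that calls too many probe sets.

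An axis of spread among HS rats was shared in part with the inbred rats. The first axis of the differences between arrays of a strain held 32.3% of that spread, and across probe sets it correlated with the first residual component of HS rats (r = 0.695), which held 18% of theirs. Along it, Cd36 had a slope of -0.80 per SD of the score, and the 2 BUF arrays stood 3.76 HS SDs apart. The score averaged -0.20 ± 1.02 in intolerant and 0.20 ± 0.96 in normal rats (SD, n = 23 each, two-sided permutation test with 100000 resamples, p = 0.189). With the score as a covariate all 3 lists kept an adjusted p under 0.05 by camera with the preset correlation. That setting called 3 or more lists in 87 of 100 splits, so this cannot decide whether the axis is a cause. Oxidative phosphorylation fell with the score (camera, adjusted p = 8.92e-05), and intolerant rats had the lower mean score. Fatty acid and triglyceride synthesis (adjusted p = 0.776) and glycolysis (adjusted p = 0.928) were not called along the score. The axis, differences between genotypes, glucose tolerance and chance stay open.

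Some levels of a single strain appeared in no HS rat. In 8 genes the strain lay at least 2 above all other inbred arrays, and 4 of them (50%, exact 95% interval 15.7 to 84.3), Cyp17a1 (BN), Ndnf (M520), RT1-A3 and RT1-N2 (WKY, in one gene complex), had no HS rat past the midpoint between the other strains and the level expected of 1 copy. If the copies of a gene add up, 1 copy lowers a log2 level by less than 1 and would not be hidden in these 4 genes, but recessive levels and levels set by another gene were not tested and stay open. Among 7 genes at least 2 lower in a strain, 5 had no HS rat near the strain. If copies add up, 1 copy would give 9.17 for Echdc2 and 10.3 for Cyp4v3. The lowest HS rats were at 9.97 and 10.9, which argues against masked single copies in Echdc2 and Cyp4v3 under this additive model. For Cyp2c7 the lowest HS rat, at 13.2, was close to the 12.9 expected of 1 copy. HS rats of Scd and Eri2 fell below that level, so masking stays possible for Cyp2c7, Scd and Eri2. Whether the strain's gene region is rare among these HS rats cannot be told apart from other causes, since 0 of the 8 genes had another within 50 genes on its chromosome (order from GRCr8).

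Differences between strains could come from sequence differences under the probes of 1 probe set. Of 848 pairs of gene and strain called with a difference of 1 or more, 120 (75 genes) had another bright probe set. The other probe set differed the same way in 106 of them (88.3%), was called the same way in 70, and had a median 0.660 of the first one's difference. Pairs are not independent, since a gene can count in several strains. By gene, taken at its largest difference, 66 of 75 differed the same way. This argues against probe binding as the main cause over these 120, as far as a gene's probe sets read different sequence. That was not checked. In 26 of the pairs the other probe set showed under 0.25 of the difference, where probe binding stays open, as do alternative transcript ends. It also stays open for Echdc2, Scd, Cyp17a1, Mlc1 and RGD1309362, which had no other probe set. No biological explanation was tested beyond the strain itself.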
